A study of Mus musculus with 6 samples.

How the data were processed

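Liver RNA of 6 mouse samples was measured by RNA sequencing. RNA was extracted with an RNeasy kit and libraries were made with a SMARTER mRNA-seq kit, per the labels' protocols. The authors deposited a table of counts per gene symbol for the 6 libraries, with whole numbers whose totals differ between libraries and with no normalization. The authors also deposited a table of FPKM values for the same libraries. Dividing the deposited counts by the deposited FPKM values gave a gene length that agreed between libraries to a relative difference of 1e-06, and lay within 0.01 bases of a whole number for 99.9% of genes. Each FPKM value was therefore the count divided by a fixed gene length and by the library's own total, and it carries no measurement beyond the counts. The submitters' processing notes list the genome builds GRCm38, mm10 and hg38 with no role for any of them. The aligner, the counting program, its treatment of strand and of reads that match several genes, and the annotation are not given in the sources used here. Without these, counts of genes with near-identical copies, of overlapping genes and of antisense pairs are uncertain.

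Samples were grouped by the labels into 3 PBS and 3 DOX livers, and each column was matched to its sample by title. Total counts were 40606190, 40592030 and 41921404 for PBS 1 to 3, and 40298256, 36374072 and 32476725 for DOX 1 to 3. The table held 0 entries that name no gene and 0 columns of other samples. Libraries of the same group differed far more than sampling noise, with chi-square values per degree of freedom of 28.2 to 78.5, so no library was taken as a copy of another; this does not show whether each came from a separate animal. Intervals and p-values take no account of PCR duplicates, since molecular identifiers are not mentioned in the sources used here.

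The test for single genes was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, with robust estimation) of DOX against PBS, on the deposited counts of all 6 libraries with group as the only term. Genes were kept by edgeR's filterByExpr with its default minimum count of 10 and minimum total of 15, which left 14681 genes, and libraries were scaled by TMM. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes and CPM come from this fit. TMM factors were 1.07, 1.08 and 1.019 for PBS 1 to 3 and 0.938, 0.933 and 0.97 for DOX 1 to 3. The biological coefficient of variation was 0.155.

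The gene lists, the named-gene rule, the main test and most of the alternatives were chosen before the data were examined. The 31 lists covered cholinergic genes, activated and resting stellate cells, extracellular matrix, TGF-beta signalling, bile duct, macrophage, neutrophil, lymphocyte and endothelial markers, hepatocyte function, cytochromes P450, bile acids, heme, antioxidant genes with Mallory body proteins, acute phase, cytokines, interferon response, cell cycle, lipogenesis, sterol synthesis, fatty acid oxidation, endoplasmic reticulum stress, mitochondrial stress, mitochondrially encoded genes, the clock, immediate early genes, erythroid, pancreatic, adipose and muscle genes, and genes that differ between the sexes. Of 751 list entries, 26 had no match in the table and 13 were matched through the RefSeq names of mitochondrial genes. Lists with at least 5 tested members, 30 in all, were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation. Named genes were Bche, Acta2, Col1a1, Col3a1, Krt19, Chrm3 and Tgfb1; the 12 genes of largest change in each direction among called genes with a mean of at least 1 CPM and groups that did not overlap; up to 4 called members of each list by smallest p, or 2 where none was called; and the 5 genes of smallest p in each direction. Predicted genes, clone names, pseudogenes and receptor segments were left out of the largest changes. Members named to spell out a small count, the gene Chrm2, and the gene families of the closing observations fall outside the rule and were chosen after their values were seen. The same holds for the mitochondrial enzymes Acadm, Acadvl, Acadl, Hadhb and Hadha of the fatty acid oxidation list. Some genes that the rule names are not reported here. Gene positions came from the RefSeq annotation of GRCm38.p6, in which 14438 of the tested symbols were found.

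The procedure was tested on simulated counts with the means and library sizes of this comparison over 14681 genes. edgeR recovered 70% of 100 genes changed 2-fold and 94% of 100 genes changed 4-fold, and 8.38% of its calls were false. DESeq2 recovered 72% and 94%, with 15.3% false calls. In a simulation over 14523 genes camera called the list that had been moved and 0 of 30 unmoved lists. The simulated genes varied independently and the lists were drawn at random, so false calls of lists whose genes vary together were not probed. The simulation for single genes changed 200 genes, whereas 27.5% of tested genes were called in the real comparison.

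The alternatives were RLE factors, upper-quartile factors or library size alone in place of TMM; no filter on low counts, or at least 1 CPM in 3 libraries; edgeR without robust estimation; the replicate number as a block; each library left out in turn; DESeq2 1.42.0; limma-voom; limma on the deposited FPKM values as log2(FPKM + 1) or log2(FPKM + 0.1), for genes with at least 1 FPKM in 3 libraries, or with no filter; adjusted p thresholds of 0.01 and 0.1; and a minimum 2-fold change. Fold changes on a log2(FPKM + pseudocount) scale understate those of low genes. An alternative chosen after the data were seen removed trends of each library with gene length and GC content by spline curves of 4 degrees of freedom, for the 94.8% of tested genes with a GC value. No livers given DOX without the knock-in genotype were analysed here.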

Results

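Messenger RNA was sequenced from 6 mouse livers, of which 3 carried the label PBS (phosphate-buffered saline) and 3 the label DOX. All 6 had the genotype label BucheKI/KI-Hep, and the series describes Buche, butyrylcholinesterase, as overexpressed in hepatocytes. Butyrylcholinesterase is a secreted liver enzyme that hydrolyses choline esters, and its gene is named Bche in the deposited tables. All 6 livers had also received DDC, the usual abbreviation in liver work for a porphyrinogenic compound that injures bile ducts and scars the tissue around them, while DOX is commonly short for doxycycline, a drug used to switch on engineered genes. The labels expand neither abbreviation, and the prefix S2W of the sample titles is likewise not explained. The total count per library ranged from 32476725 in DOX 3 to 41921404 in PBS 3, and 14681 of the 22183 gene symbols passed the filter on low counts. Counts of mitochondrially encoded genes made up 3.45 to 4.58% of the total in the PBS libraries and 5.11 to 6.81% in the DOX libraries. Levels are given as normalised read counts (CPM, counts scaled to a common library total) with their SD over 3 libraries per group. The labels do not say that the 3 samples of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

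The comparison set DOX against PBS livers, all given DDC and all of the knock-in genotype. It cannot separate an effect of raised hepatocyte butyrylcholinesterase from an effect of the DOX agent itself. The series title names the activation of hepatic stellate cells and muscarinic signalling as the readouts of interest. Hepatic stellate cells store vitamin A at rest and become collagen-producing myofibroblasts after injury. DOX livers held 9.94-fold more Bche mRNA than PBS livers. The fibrillar collagen genes Col1a1 and Col3a1 were 2.76-fold lower, whereas Acta2, the myofibroblast actin, did not pass the test. Most measured genes of the lists for fatty acid oxidation, proliferation and the interferon response fell, with medians of -1.09, -1.54 and -0.95 on the log2 scale. The fatty acid oxidation list also holds other targets of the nuclear receptor PPAR-alpha. Enzymes of amino acid metabolism, several cytochromes P450, sterol synthesis genes and endothelial markers rose, while other cytochromes P450 fell.

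Bche was measured at 187 ± 16.5 CPM in PBS and 1856 ± 87.7 CPM in DOX livers (SD, n = 3 each). The log2 fold change was 3.31 (SE 0.14, adjusted p = 1.65e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and all 3 DOX libraries lay above all 3 PBS libraries. In the mouse assembly GRCm38.p6 the Bche gene spans positions 73635805 to 73708436 of chromosome 3. The deposited values are totals per gene symbol, so transcripts of the native gene and of the knock-in are not separated. All adjusted p-values of single genes below come from the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over the 14681 genes.

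**Figure D1:**
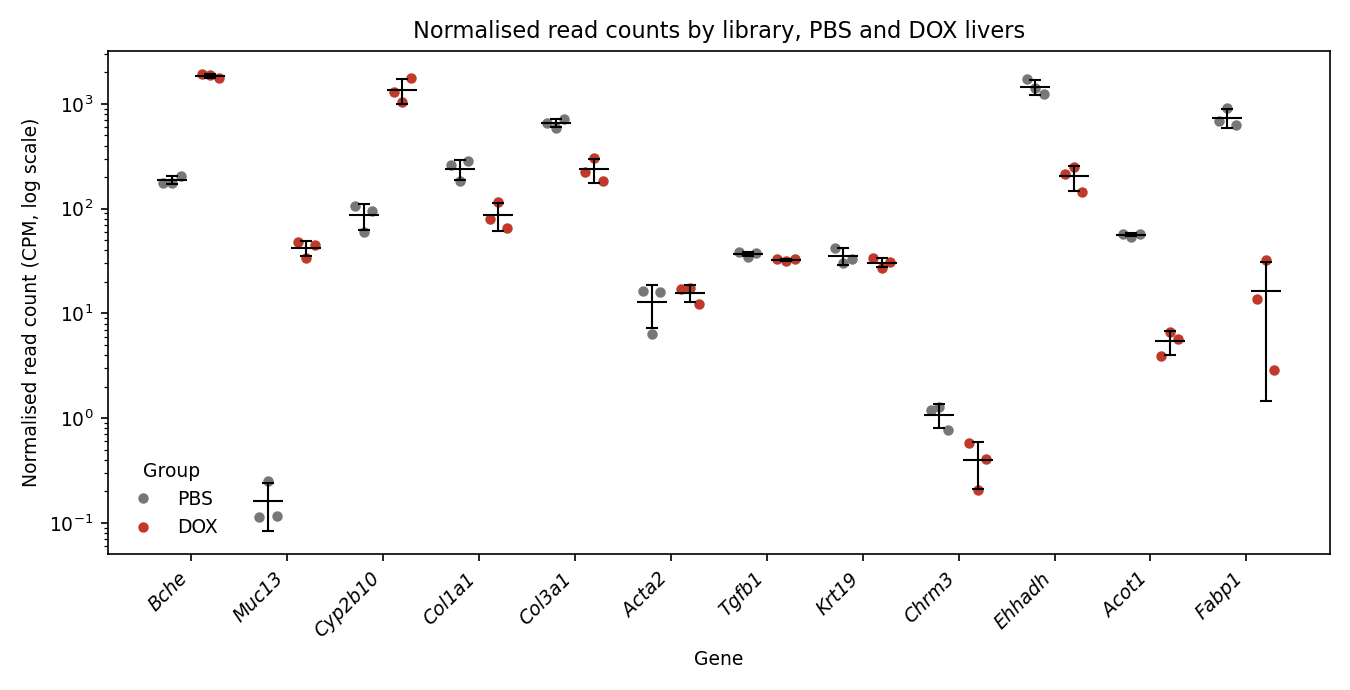
Normalised read counts (CPM, logarithmic axis) of 12 genes in each library, with grey points for the 3 PBS libraries, red points for the 3 DOX libraries, and black bars for the mean and SD of a group. Bche lies near 187 CPM in PBS and 1856 CPM in DOX livers, Col1a1 and Col3a1 are lower in every DOX library, and the groups overlap for Acta2.

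Over all genes, 1975 were higher and 2062 lower in DOX livers at an adjusted p under 0.05 in edgeR's quasi-likelihood test, together 27.5% of those tested. At least a 2-fold change was seen for 387 of the higher and 733 of the lower genes. The groups did not overlap for 44.1% of the genes, against 10% by chance for 3 libraries against 3. Higher genes made up 48.9% of the calls. Scaled by library size alone, with no correction for composition, they made up 23.1% (1028 higher, 3429 lower), and the median of all genes moved to -0.16 on the log2 scale. The count of higher genes was 1233 without PBS 2, 1229 without PBS 3 and 1208 without DOX 3, and that of lower genes 1305 without PBS 2 and 1329 without DOX 3.

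The gene with the smallest p and the largest rise was Muc13, a membrane mucin of epithelial surfaces, at 0.161 ± 0.0779 CPM in PBS and 42.3 ± 7.26 CPM in DOX livers (SD, n = 3; log2 fold change 8.0, SE 0.25, adjusted p = 1.42e-08). Sult1e1, the estrogen sulfotransferase, rose 46.8-fold (adjusted p = 0.000384). Cyp2b10, a cytochrome P450 induced through the receptor CAR, went from 86.9 ± 24.2 to 1358 ± 360.0 CPM (SD, n = 3; log2 fold change 3.97, adjusted p = 5.59e-05). Further large rises were those of the metalloproteinase inhibitor Timp4 (29.3-fold), Bhlha15 (10.1-fold), the macrophage chitinase-like gene Chil3 (9.87-fold), Fam107a (9.43-fold), Gstm5 (8.57-fold) and Tmem100 (8.13-fold). Timp4, Bhlha15, Fam107a and Tmem100 had PBS means of only 0.0998, 0.2, 0.77 and 0.338 CPM. Timp4 stood at 1.59, 1.71 and 5.81 CPM in DOX 1 to 3. It did not pass with limma on log2(FPKM + 1) without the filter (adjusted p = 0.0858). Ssbp2, Cyp2c54 and Sdsl completed the higher genes of smallest p, with log2 fold changes of 2.88, 1.89 and 1.61. Cyp1a1, a target of the aryl hydrocarbon receptor, went from 0.929 ± 0.221 to 12.4 ± 11.5 CPM (adjusted p = 0.0306), and its adjusted p ran up to 0.122 when single libraries were left out, passing 0.05 without PBS 1 (0.114), PBS 2 (0.105), PBS 3 (0.122) or DOX 1 (0.0597), in a range of 3.46e-05 to 0.122 over the alternatives.

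Fabp1, the liver fatty acid binding protein, showed the largest fall, from 738 ± 148 CPM in PBS to 16.3 ± 14.8 CPM in DOX livers (SD, n = 3; log2 fold change -5.50, SE 0.99, adjusted p = 0.0202). The DOX libraries differed among themselves in Fabp1, at 13.8, 32.1 and 2.86 CPM, and its adjusted p was 0.0586 without PBS 1, 0.0574 without PBS 2, 0.0612 without PBS 3 and 0.0856 without DOX 1, in a range of 1.19e-10 to 0.0856 over the alternatives. Other large falls were those of Ly6d (24.6-fold), the chemokine Ccl20 (20.8-fold), the carboxylesterase Ces3a (19.5-fold), the DNA repair genes Fignl1 (14.4-fold) and Rad51b (14.1-fold), Themis (13.7-fold), the peroxisomal thiolase Acaa1b (13.0-fold), the carbonic anhydrase Car3 (13.0-fold) and the sulfotransferase Sult2a8 (11.2-fold). Among the DOX libraries, Ly6d, Ccl20, Ces3a and Themis were highest in DOX 2, at 5.835, 0.295, 1.415 and 1.65 CPM. Their DOX means were 3.02, 0.128, 0.7855 and 0.769 CPM. Over the alternatives, their log2 fold changes ran from -5.515 to -4.298, -5.842 to -1.961, -4.991 to -2.68 and -4.969 to -1.385. Cyp4a14, a fatty acid omega-hydroxylase, was 12.9-fold lower with an adjusted p of 0.0494, which rose to 0.122 without PBS 1, 0.101 without PBS 2, 0.124 without PBS 3 and 0.149 without DOX 1, in a range of 0.000232 to 0.149. The lower genes of smallest p were Acot1 and Acot3, acyl-CoA thioesterases, Vnn1, Cyp4a31 and Ehhadh, with log2 fold changes of -3.38, -2.58, -3.06, -3.07 and -2.85. Acot1 with Acot3, the Cyp4a genes, Cyp2b10 with Cyp2b9, the Cyp2c genes, Ces3a, Sult2a8 and the Serpina3 genes have closely similar copies, and the sources used here do not say how reads shared between copies were counted.

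Gene lists chosen before the data were examined were then compared as groups, by counting members that passed the edgeR test and by camera, a test of whether a list moved relative to all other genes. With camera's preset correlation of 0.01, 6 of 30 lists were higher and 8 lower in DOX livers, and with an estimated correlation 0 were called, with 5 at an unadjusted p under 0.05. Under other divisions of the same 6 libraries camera called up to 13 lists in a single direction, so the member counts are given first. The plot of list members shows each tested gene of all 31 lists.

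**Figure D2:**
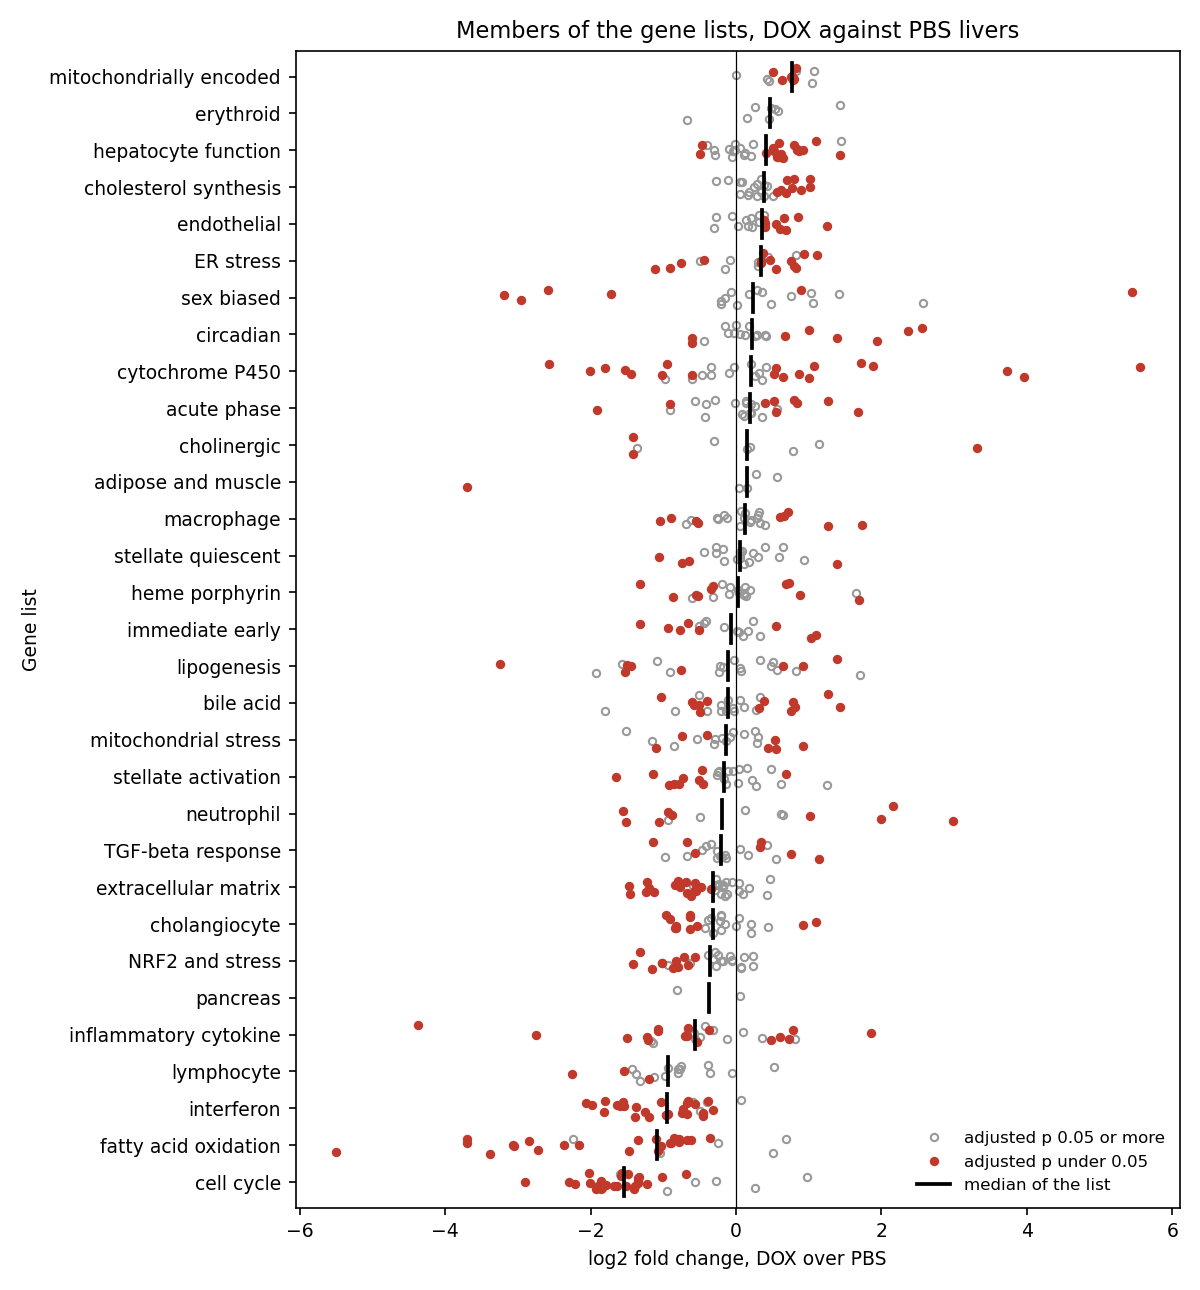
Log2 fold changes (DOX over PBS) of the tested members of the 31 gene lists, one point per gene and one line per list, with filled points for genes at an adjusted p under 0.05 in the edgeR test and black bars for the list medians. Members of the cell cycle, fatty acid oxidation and interferon lists lie mostly below 0, with medians of -1.54, -1.09 and -0.95.

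Of 36 extracellular matrix genes, 17 fell in DOX livers and the others did not pass the edgeR test (18 fell and 1 rose when adjusted over the list alone). Col3a1 went from 657 ± 60.8 CPM in PBS to 238 ± 63.1 CPM in DOX (SD, n = 3; log2 fold change -1.47, SE 0.18, adjusted p = 0.000395). Col1a1 went from 241 ± 52.0 to 87.5 ± 25.7 CPM (SD, n = 3; log2 fold change -1.46, SE 0.23, adjusted p = 0.00263). Col1a2 and the small proteoglycan gene Lum fell by 1.12 and 0.68 on the log2 scale. The list median was -0.32, and camera gave adjusted p = 1.11e-05 with the preset correlation and adjusted p = 0.581 with an estimated correlation. Without PBS 1 or without DOX 3 the number of matrix genes that fell was 11, and 2 rose without DOX 3.

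Of 25 genes raised in activated stellate cells, 9 fell, among them Thy1, which fell by 1.15 on the log2 scale, and Pdgfra rose by 0.69 on the log2 scale (9 fell and 2 rose when adjusted over the list alone). The number that fell was 2 without PBS 1, 5 without PBS 3, 5 without DOX 1 and 1 without DOX 3, and 2 rose without PBS 1 or PBS 3. Camera did not call this list (adjusted p = 0.245), although its adjusted p was 0.0362 without PBS 2, within a range of 0.0362 to 0.542 over the alternatives. Acta2 was measured at 13.0 ± 5.67 CPM in PBS and 15.6 ± 2.90 CPM in DOX (SD, n = 3; log2 fold change 0.27, SE 0.35, adjusted p = 0.611), and its log2 fold change was -0.05 without PBS 2, the library with the lowest Acta2 level. Of 22 genes of resting stellate cells, Hhip rose by 1.39 on the log2 scale, whereas Steap4, the retinol-esterifying enzyme Lrat and Colec11 fell, with log2 fold changes of -1.07, -0.74 and -0.65 (1 rose and 3 fell when adjusted over the list alone; camera adjusted p = 0.956). The number that fell was 1 without PBS 1 and 5 without DOX 2, and 2 rose without PBS 1. Lrat no longer passed without PBS 1 (adjusted p = 0.0591) or PBS 3 (0.0514), and Colec11 no longer passed without PBS 1 (0.0872), PBS 2 (0.081) or DOX 3 (0.0585); over all alternatives the adjusted p ran from 0.00165 to 0.0591 for Lrat and from 0.0029 to 0.0872 for Colec11.

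Of 22 genes of TGF-beta signalling, the main fibrogenic cytokine pathway, 4 rose (Smad7, Tgfbr3, Smad2 and Smad4) and 3 fell (Ltbp2, Pmepa1 and Tgfb2), or 6 and 4 when adjusted over the list alone. Smad7 rose by 1.14 on the log2 scale (adjusted p = 8.08e-05), and Pmepa1 fell by 0.67 on the log2 scale. Tgfb1 itself stood at 37.0 ± 1.96 CPM in PBS and 32.5 ± 0.752 CPM in DOX (SD, n = 3; log2 fold change -0.19, SE 0.10, adjusted p = 0.173). Scaled by library size alone, its log2 fold change was -0.34 with an adjusted p of 0.0227, in a range of 0.0199 to 0.37 over the alternatives. The same scaling gave 2 members of the list that rose and 8 that fell. The number that rose was also 2 without PBS 1, PBS 2, PBS 3 or DOX 3, and camera did not call the list (adjusted p = 0.774).

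Of 9 measured cholinergic genes, Bche rose, the muscarinic receptor gene Chrm3 and the nicotinic receptor gene Chrna4 fell, and the other 6 did not pass (1 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.0589). The other measured muscarinic receptor gene, Chrm2, pointed upward but did not pass (log2 fold change 1.14, adjusted p = 0.139). Chrm3 was close to the lower limit of measurement, at 1.08 ± 0.271 CPM in PBS and 0.4 ± 0.188 CPM in DOX (SD, n = 3; log2 fold change -1.42, SE 0.45, adjusted p = 0.0348). Its adjusted p was 0.0983 without PBS 1, 0.113 without PBS 2, 0.0893 without DOX 2 and 0.0878 without DOX 3, in a range of 0.0196 to 0.113 over the alternatives. Chrna4 stood at 3.46 ± 1.68 and 1.28 ± 0.489 CPM (adjusted p = 0.0232), with an adjusted p of 0.102 without PBS 1, 0.0538 without PBS 3 and 0.0743 without DOX 3, in a range of 0.0023 to 0.11. Camera's adjusted p for this list was 0.015 without DOX 3, and ran from 0.00551 to 0.237 over the alternatives, and 2 of its genes rose without DOX 1. Camera's direction for the list was upward in the main test. The list holds Bche, the gene described as overexpressed, so these camera values do not test a response of the other cholinergic genes.

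The fatty acid oxidation list joins enzymes of that pathway with other targets of the nuclear receptor PPAR-alpha. Its genes fell most broadly among the metabolic lists. Of 28 measured, 23 fell and the other 5 did not pass (25 fell and 2 rose when adjusted over the list alone, and 1 rose without DOX 1). Acot1 went from 56.3 ± 1.89 to 5.41 ± 1.38 CPM (adjusted p = 1.2e-06), Vnn1 from 28.4 ± 5.34 to 3.42 ± 0.498 CPM (adjusted p = 2.24e-06), and the peroxisomal enzyme Ehhadh from 1460 ± 245 to 203 ± 53.9 CPM (adjusted p = 4.36e-05; SD, n = 3 each). The mitochondrial enzymes Acadm (-0.24, not called), Acadvl (-0.36), Acadl (-0.62), Hadhb (-0.67) and Hadha (-0.78) moved less than the list median of -1.09 (log2). Camera called the list lower (adjusted p = 7.63e-31 with the preset correlation, adjusted p = 0.273 with an estimated correlation). Of 24 lipogenic genes, 3 rose (Mlxipl, Srebf1 and Lpin1) and 5 fell, among them the desaturase Fads2 (-1.49), the elongase Elovl5 (-1.44) and the lipid droplet gene Cidec (-3.25), or 3 and 6 when adjusted over the list alone (camera adjusted p = 0.435). In that list 1 gene rose without PBS 3, and 3 genes fell without PBS 3 or DOX 3. Of 25 genes of sterol synthesis, 9 rose and the others did not pass (9 when adjusted over the list alone), among them Mvk (1.02), Lss (1.02), Msmo1 (0.80) and Fdft1 (0.69). Camera called this list higher (adjusted p = 0.000463 with the preset correlation, adjusted p = 0.659 with an estimated correlation).

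Of 31 genes of hepatocyte function, 15 rose and 2 fell, among them Gys2 (15 and 3 when adjusted over the list alone). Members that rose included Tat, the tyrosine aminotransferase (1.43), the urea cycle genes Ass1 (0.87) and Arg1 (0.84), and the histidine-degrading enzyme Hal (0.83). The number that rose was 9 without PBS 1 and 7 without PBS 2, and the number that fell was 4 without DOX 2 and 1 without PBS 1, PBS 3, DOX 1 or DOX 3. Camera called the list higher (adjusted p = 0.00053 with the preset correlation, adjusted p = 0.581 with an estimated correlation). Among 31 genes of cytochromes P450 and pericentral hepatocytes, 11 rose and 8 fell (13 and 10 when adjusted over the list alone, 9 and 11 when scaled by library size alone). Cyp2b10, Sult1e1, Cyp2c54 and Cyp2c50, which rose, had the smallest p. The 8 that fell were Slc1a2 (-2.57), Rgn (-2.01), Cyp2c55 (-1.80), Cyp2b9 (-1.52), Lect2 (-1.44), Cyp2j5 (-1.02), Cyp2a5 (-0.94) and Axin2 (-0.60). Camera did not call this list (adjusted p = 0.0529, with values of 0.0123 to 0.211 over the alternatives, among them 0.0201 without PBS 1, 0.0386 by library size alone and 0.0467 without DOX 3), and 5 of its genes fell without DOX 1.

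Of 27 genes of bile acid synthesis and transport, 7 rose and 6 fell (7 and 8 when adjusted over the list alone, 5 and 8 when scaled by library size alone), with log2 fold changes of 1.44 for the transporter subunit Slc51b, 1.26 for the hydroxylase Cyp39a1, 0.78 for the uptake carrier Slc10a1 and 0.82 for Slco1a4. Camera did not call the list (adjusted p = 0.774), and its direction was upward while the median was -0.12 and the mean -0.05. Without PBS 1, PBS 3 or DOX 3 the number that fell was 3, and without DOX 1 it was 2. Of 23 genes of heme and iron metabolism, 4 rose and 6 fell (4 and 7 when adjusted over the list alone; camera adjusted p = 0.774). Hamp, which encodes the iron hormone hepcidin, went from 371 ± 54.8 to 1199 ± 202 CPM (SD, n = 3; log2 fold change 1.69, adjusted p = 9.77e-05), the heme oxygenases Hmox1 and Hmox2 rose by 0.87 and 0.72 on the log2 scale, and Alas1, the first enzyme of heme synthesis, rose as well. Uros, a later enzyme of heme synthesis, fell by 1.32 on the log2 scale. The number of heme genes that fell was 2 without PBS 2 or DOX 1 and 3 without PBS 3 or DOX 3.

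Proliferation genes were lower in DOX livers. Of 32 measured, 26 fell and the other 6 did not pass (29 fell when adjusted over the list alone, and 1 rose without PBS 1). The replication helicase genes Mcm4 and Mcm2 fell by 1.89 and 1.68 on the log2 scale, E2f1 by 2.0 and the mitotic kinase gene Aurka by 2.30 (adjusted p = 7.66e-05, 0.000284, 0.00031 and 0.000595). Camera called the list lower (adjusted p = 1.07e-16 with the preset correlation, adjusted p = 0.273 with an estimated correlation). Of 30 interferon response genes, 26 fell and the other 4 did not pass (27 fell when adjusted over the list alone). Oasl2, Ifit3 and Iigp1 fell by 1.99, 1.59 and 0.96 on the log2 scale, and camera called the list lower (adjusted p = 2.37e-14 with the preset correlation, adjusted p = 0.273 with an estimated correlation).

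Of 29 cytokine, chemokine and adhesion genes, 12 fell and 5 rose, namely Ccl6, Ccl9, Ccl24, Cxcl13 and Il18 (14 and 6 when adjusted over the list alone). Cxcl10, a chemokine induced by interferon, went from 9.53 ± 2.29 to 1.42 ± 0.359 CPM (SD, n = 3; adjusted p = 8.08e-05), Csf1 fell by 0.67 on the log2 scale and Ccl6 rose by 0.79. Camera called the list lower (adjusted p = 0.00389 with the preset correlation, adjusted p = 0.273 with an estimated correlation). The number that rose was 3 without PBS 1 or DOX 1 and 2 without PBS 2 or PBS 3. Of 25 acute phase genes, 7 rose and 2 fell, Il1rn and Orm2 (7 and 2 when adjusted over the list alone, 5 and 5 when scaled by library size alone), with Serpina3k (1.68), the metallothionein Mt2 (1.27) and Serpina3m (0.83) among the rises. Camera did not call that list (adjusted p = 0.0589), with values of 0.0119 to 0.473 over the alternatives, among them 0.0119 without PBS 3, 0.0152 without DOX 1 and 0.025 without DOX 3, and 5 of its genes fell without DOX 2.

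Markers of other liver cell types moved in different directions. Of 20 endothelial markers, 9 rose and the others did not pass (9 when adjusted over the list alone), with log2 fold changes of 0.66 for Ptprb, 0.85 for Flt1, 0.69 for Pecam1 and 0.55 for Oit3. Camera called them higher (adjusted p = 0.0022 with the preset correlation, adjusted p = 0.643 with an estimated correlation), and 5 rose without PBS 2. Of 25 bile duct markers, 9 fell and 2 rose, among them Mmp7 (10 and 2 when adjusted over the list alone). Sox9, Cftr, Sox4 and Elf3 fell by 0.96, 0.90, 0.83 and 0.83 on the log2 scale, whereas Krt19, the keratin of bile duct cells, stood at 35.3 ± 6.39 and 30.6 ± 3.18 CPM (SD, n = 3; log2 fold change -0.20, adjusted p = 0.294). Camera called the bile duct list lower (adjusted p = 0.0107 with the preset correlation, adjusted p = 0.659 with an estimated correlation), but not without PBS 1 (adjusted p = 0.107) or without DOX 2 (0.473), in a range of 0.00146 to 0.473 over the alternatives. In that list 1 of the genes rose without PBS 2, PBS 3, DOX 1 or DOX 3.

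Of 26 macrophage markers, 5 rose (Cd163, Vsig4, Marco, Gpnmb and Ctss) and 4 fell (Ccr2, Itgax, Ms4a7 and Cd5l), or 9 and 5 when adjusted over the list alone and 4 and 7 when scaled by library size alone, and camera did not call them (adjusted p = 0.437). Among these Cd163, Vsig4, Ccr2 and Itgax, the members of smallest p, had log2 fold changes of 1.73, 0.72, -1.05 and -0.55. The number of macrophage markers that rose was 8 without DOX 2, and the number that fell was 2 without PBS 2 or DOX 3. Of 14 neutrophil markers, 4 rose (Ngp, Stfa2l1, Retnlg and Mmp8) and 5 fell (Mmp9, Csf3r, Cxcr2, Clec4e and Acod1), the same numbers as adjusted over the list alone, and camera did not call them (adjusted p = 0.836; median -0.19, mean 0.16). Without 1 library these numbers went as low as 1 that rose (DOX 1; 2 without PBS 1, PBS 3 or DOX 3) and 2 that fell (PBS 1, PBS 3 or DOX 3; 3 without PBS 2). Ngp had an adjusted p of 0.0132, and of 0.0555 without DOX 1, in a range of 0.000819 to 0.0578. Of 17 lymphocyte markers, Nkg7, Cd79b and Cd8b1 fell (2 when adjusted over the list alone), each at a mean of 1.51 CPM or less in PBS livers. None of those 3 passed without PBS 1, and 1 of them passed when any other single library was left out. Camera called the lymphocyte list lower (adjusted p = 0.00859 with the preset correlation, adjusted p = 0.581 with an estimated correlation), but gave 0.0506 when scaled by library size alone and 0.119 under a stricter filter, in a range of 0.000997 to 0.119.

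Of 28 genes of antioxidant defence, NRF2 targets and Mallory body proteins, 11 fell and the others did not pass (11 when adjusted over the list alone; 1 rose without DOX 2). Among them were Krt8 and Krt18, the keratins of Mallory bodies (-0.80 and -0.56), Ugdh (-1.42) and Gclc, the rate-limiting enzyme of glutathione synthesis (-0.87). Camera called the list lower (adjusted p = 0.00049 with the preset correlation, adjusted p = 0.581 with an estimated correlation). Of 21 genes of the unfolded protein and integrated stress responses, 10 rose, among them Manf (0.93), Calr (0.82), Ppp1r15a (0.79) and Atf4 (0.56), and 4 fell (Ddit3, Atf3, Dnajb9 and Nupr1), or 13 and 5 when adjusted over the list alone. Camera called that list higher (adjusted p = 0.0211 with the preset correlation, adjusted p = 0.643 with an estimated correlation), but not without PBS 1 (adjusted p = 0.27, in a range of 0.00342 to 0.27). The number that rose was 6 without PBS 1 or PBS 2, and the number that fell was 1 without PBS 2 or DOX 3 and 2 without DOX 1.

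Of 13 protein-coding genes of the mitochondrial genome, 7 rose and the others did not pass (11 rose when adjusted over the list alone), with log2 fold changes of 0.82 for COX3, 0.79 for ND1, 0.75 for ND4 and 0.77 for ND5. Camera called them higher (adjusted p = 5.71e-05 with the preset correlation, adjusted p = 0.581 with an estimated correlation). The number that rose was 4 when scaled by library size alone and 4 without PBS 3. Of 21 nuclear genes of mitochondrial stress, 4 rose (Atf5, Clpp, Clpx and Psph) and 3 fell (Mthfd1l, Aldh18a1 and Lonp1), or 5 and 4 when adjusted over the list alone, against 2 and 7 when scaled by library size alone. Camera did not call that list (adjusted p = 0.836), and 5 of its genes fell without DOX 2.

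Of 20 clock genes, 6 rose (Bmal1, Npas2, Per1, Cry2, Nr1d1 and Ciart) and 2 fell (Per3 and Wee1), or 7 and 2 when adjusted over the list alone. Bmal1, a core activator of the clock, went from 2.33 ± 0.418 to 13.8 ± 4.10 CPM (SD, n = 3; adjusted p = 0.000112), Ciart rose by 1.94 on the log2 scale and Per1 by 1.0. Camera called the list higher (adjusted p = 0.00389 with the preset correlation, adjusted p = 0.273 with an estimated correlation), and 1 of its genes fell without PBS 1 or DOX 1. The labels do not give the hour at which the livers were taken. Of 18 immediate early genes, 3 rose (Dusp1, Klf2 and Klf4) and 5 fell (Jun, Egr2, Ier3, Btg2 and Maff), the same numbers as adjusted over the list alone (camera adjusted p = 0.734). The number that fell was 3 without PBS 2, PBS 3 or DOX 1.

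Markers of blood and neighbouring tissue gave few calls. Of 8 erythroid genes, 0 passed edgeR's quasi-likelihood test over all genes or over the list alone, 1 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0, while 4 rose without DOX 1 (camera adjusted p = 0.413, and 0.00206 without DOX 1, in a range of 0.00206 to 0.872). Bpgm and Slc4a1, the erythroid genes of smallest p, had log2 fold changes of 0.27 and 1.43 (adjusted p = 0.0935 and 0.157). The pancreatic genes Cela1 and Cela2a, the 2 of that list that were measured, had log2 fold changes of 0.06 and -0.81, and edgeR, DESeq2 and limma-voom called 0 of them, with 0 at an unadjusted p under 0.05 in edgeR. Of 5 adipose and muscle genes Car3, which hepatocytes also express, fell (1 when adjusted over the list alone; camera adjusted p = 0.774, with a median of 0.15 and a mean of -0.53). Of 20 genes that differ between the sexes, 2 rose, among them Cyp17a1, and Acot3, Mup3, Mup20 and Cyp2b13 fell (2 and 4 when adjusted over the list alone). Camera did not call that list (adjusted p = 0.92) and gave it a downward direction, against a median of 0.23 and a mean of 0.17. Cyp17a1 no longer passed without PBS 1 (adjusted p = 0.0518) or PBS 2 (0.0573), in a range of 0.000737 to 0.0896. In that list 1 gene rose without PBS 1, and 2 genes fell without PBS 3 or DOX 3. The Y-linked gene Ddx3y was read in all 6 libraries at 63.5 to 90.4 CPM, and Xist at no more than 0.0954 CPM.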

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

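The fit with length and GC trends removed was chosen after the result was seen. Bche kept its direction and its call in all 19 alternatives, with log2 fold changes of 3.12 to 3.39, and the number of called list members stayed within 1.5 times of 321. Of 137 named genes, 25 lost or gained a call in at least 1 alternative, 14 of them when a library was left out and 1 under another scaling. At a depth of 32476725 to 41921404 counts, genes near 1 CPM such as Chrm3, Cd8b1 and Nkg7 rest on few reads, and their calls were among those lost. Some genes and lists gave no value under a stricter filter or the length and GC correction, since they were then not tested.

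The 1975 higher genes became 1028 when scaled by library size alone, 837 with limma on log2(FPKM + 1), 831 on log2(FPKM + 0.1) and 544 without the FPKM filter, 387 with a minimum 2-fold change and 859 at an adjusted p under 0.01. The 2062 lower genes became 3429 by library size alone, 733 with the 2-fold minimum and 903 at 0.01. FPKM values are scaled by library totals, as in the fit by library size alone, and the higher share of calls was 23.1% there, 23.8%, 23.9% and 19.2% in the FPKM fits and 48.9% with TMM. Leaving out a library gave 1208 to 2440 higher and 1305 to 2348 lower genes. The highest of both came without DOX 2, the DOX liver nearest the PBS livers on the first principal component (23.3, against 41.2 and 53.6), and the median of fatty acid oxidation genes was then -1.36; without any other library 1208 to 1376 were higher and 1305 to 1537 lower, with fewer samples in each such fit. Why DOX 2 differs was not tested. With camera's estimated correlation the 6 higher and 8 lower lists became 0 and 0.

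The log2 fold change of Acta2 was -0.053 without PBS 2 and up to 0.481 without other libraries. That of Cela1, 0.06 and not called, was -0.102 by library size alone, -0.073 with length and GC trends removed, -0.093 with limma on log2(FPKM + 1) with or without the filter, -0.105 on log2(FPKM + 0.1), and -0.032 to 0.191 with a library left out, below or at 0 without PBS 3, DOX 1 or DOX 3. The cause of these changes was not tested. With the replicate number as a block, 1633 genes were higher and 1849 lower, and 3341 were called the same way as without it. Same-numbered samples deviated from their group means with correlations of 0.09, -0.07 and -0.13, and only number 1 correlated best with its own number. These values gave no sign that the numbers pair the samples, but so few correlations cannot exclude it.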

Other observations

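The tests of cell composition and of the DOX agent below, and the gene families described first, were chosen after the results were seen. Genes that share the start of their symbol were grouped into 174 families of at least 10 tested genes and tested with camera at the preset correlation; 17 were called, each of which had an adjusted p of 0.973 with an estimated correlation. Of 80 cytosolic ribosomal protein genes, 79 rose in DOX livers (edgeR's quasi-likelihood test) with a median log2 fold change of 0.87, 77 rose when scaled by library size alone, and 72 with limma on log2(FPKM + 1), but only 3 did so without the FPKM filter (median 0.687). The Ndufa and Ndufb families of respiratory complex I rose in 10 of 14 and 9 of 13 members, and the Cox family in 10 of 22. Scaled by library size alone, 5, 5 and 5 rose, 3 of the Cox family fell, and the family medians stayed above 0 (0.31, 0.27 and 0.26). These families were not examined with the length and GC trends removed.

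The libraries were also divided in every other way into 3 and 3. edgeR called 1975 higher and 2062 lower genes for the real groups, and 0 in either direction for the other 9 divisions, which had 85 to 714 genes at an unadjusted p under 0.05 against 5867 for the real groups. Each of those other divisions mixed PBS and DOX livers on both sides, which widens the spread within a side and makes calls unlikely. They were therefore not groupings free of the difference between PBS and DOX, for edgeR or for camera. Only the real division, 1 of 10, gave counts as large, and 10 divisions are too few to give a share under 0.05. For camera, 6 lists higher and 8 lower compare with up to 13 lists in a single direction for another division; 9 and 5 of the 10 divisions, the real one included, gave as many.

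The list of fatty acid oxidation genes and PPAR-alpha targets fell in DOX livers, with a median of -1.09. A smaller share of hepatocytes would lower hepatocyte genes in general, but the hepatocyte function list had a median of 0.416 (log2), which argues against it. Scaling of the libraries also accounts poorly for the fall, since the least negative median under 3 other scalings was -1.083. An effect of the DOX agent apart from Bche cannot be told apart from one of butyrylcholinesterase, because 0 libraries came from livers without the knock-in genotype. Both stay open.

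The extracellular matrix list, 36 tested genes, had a median of -0.318 (log2). Fewer stellate cells would lower resting stellate cell genes too, and the median of those 22 genes was 0.06, a difference of 0.375 (95% bootstrap interval 0.117 to 0.711, over genes, which are not independent). Those 22 genes ran from -1.07 to 1.39 with an SD of 0.551, Lrat, Colec11 and Steap4 fell among them, and fewer stellate cells therefore stay open. Dilution by hepatocyte RNA would lower endothelial markers as well, but their median was 0.351 (0.193 when scaled by library size alone, and 0.132 to 0.141 in the FPKM fits). In 4 of 19 alternatives some of these markers were called lower. The positive medians argue against an even dilution of all other cell types. The medians of the other cell type lists were mixed, at 0.117 for macrophage, -0.189 for neutrophil, -0.323 for bile duct and -0.94 for lymphocyte markers. Lower collagen expression per stellate cell or fibroblast was not tested and stays open, as do the DOX agent and a change in a subset of these cells.

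The ribosomal protein genes, with the kinases and gene copies of similar name left out after their values were seen, are short, with a median length of 802 bases against 3553 for all tested genes. Among short genes more rose than fell: of the 2937 shortest genes 637 were higher and 264 lower, and of the 2936 longest 277 and 422. With trends in length and GC content removed, the median of the ribosomal genes was 0.647, and under the scaling of counts least favourable to them it was 0.713, values that argue against either as the whole cause. A difference in RNA quality that acts on ribosomal protein transcripts in particular was not tested and stays open, and a rise in ribosome production in DOX livers was not tested either.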
